A study of Mus musculus with 6 samples.

How the data were processed

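RNA-seq was performed on 6 libraries of immortalised mouse preadipocytes differentiated in culture: 3 from cells given ethanol (control) and 3 from cells given 4-hydroxytamoxifen (knockout). Per the labels' protocols, the parent cells came from the inguinal fat of mice carrying floxed Tcf7l2, were sorted as CD34, Sca1 and CD29 positive cells after removal of CD31, CD45 and Ter-119 positive cells, were immortalised with SV40 large T antigen, and carried CreERT2, a Cre recombinase that 4-hydroxytamoxifen activates. Libraries were made from total RNA depleted of ribosomal RNA with a strand-specific kit, per the labels' protocols.

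The deposited file held raw read counts per Ensembl gene for 49671 genes in 6 columns, 1 per library, with no other columns of sample values and no rows for unassigned reads. Columns were assigned to samples by the library number in their titles, and samples to groups by the genotype label. The submitters' processing notes name STAR 2.5.2b, featureCounts 1.5.1, DESeq2 1.16.0 and the mouse build GRCm38, without saying what each was used for. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Reads from a gene and a gene overlapping it on the opposite strand can be told apart only if the counting used strand, so overlaps of exons were computed for the genes named in the text and are given where they exceed 10% or where the partner was far more abundant. Gene symbols were matched by Ensembl gene identifier, of which 49326 had a symbol and 345 did not. Coordinates are those of GENCODE release M21, which is on GRCm38. Its release may differ from the one used for counting.

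Differences between knockout and control were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test with robust dispersion estimates, TMM scaling, genes kept by filterByExpr, model with group as its only term). Of the listed genes, 14946 were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are knockout over control, and the standard error (SE) of a log2 fold change was taken as its size divided by the square root of its F statistic. Levels are edgeR's CPM, counts scaled to a common library size with TMM, given as mean ± SD over the 3 libraries of a group. Total counts ran from 26621293 to 33484764 per library. The common biological coefficient of variation was 5.91%.

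Before the data were examined, 23 gene lists, the test for them, the rule for naming genes and the alternatives were fixed. Each list was tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, 2-sided, Benjamini-Hochberg adjustment over the 23 lists). Camera asks whether the genes of a list rank apart from all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were run beside it. The estimated correlations ran from -0.0471 to 0.774. One cholesterol list entry, Sc4mol, is an older name of Msmo1, which the list also holds. The rule named Tcf7l2; the 10 genes with the largest rise and the 10 with the largest fall among called genes with an average log2 CPM of at least 2, no overlap between the groups and a symbol that is not a clone name; up to 3 called members per direction of each list with an average log2 CPM of at least 0; and, in a list with no called member, its 2 most abundant members. Genes outside the rule are said to have been chosen after their values were seen. Some genes that the rule named are not reported here.

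The alternatives were DESeq2 size factors, upper-quartile or total count scaling in the edgeR fit; no filter on low counts, or a CPM of at least 1 in 3 samples; DESeq2 1.42.0 (Wald test); limma-voom; a stricter adjusted p of 0.01; a test against a log2 fold change of 1 (glmTreat); and leaving out each library in turn. An alternative that left out control replicate 3 and knockout replicate 2 together was chosen after seeing the data. The labels give the groups no shared replicate numbers, so no paired fit was planned.

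The test was tried on simulated data for the same comparison: counts of 14946 genes drawn with the means and library sizes of the real libraries, 200 of them changed. With the gene-wise dispersions of the real data, edgeR recovered 44.9% of genes changed 1.25-fold, 71.4% of those changed 1.5-fold, 86% of those changed 2-fold and 100% of those changed 4-fold, and 22 of 169 calls (13%) were false. With trended dispersions 4 of 158 calls (2.53%) were false. Among unchanged genes, 5.03% had a p under 0.05 in either simulation. Far fewer genes were changed than the 3346 called in the real comparison, so the recovered and false shares may differ there. In a second simulation with a 1.3-fold rise planted in the glycolysis list, camera called that list and 0 of the other 22. Genes were drawn independently of each other there. This simulation therefore does not test camera on lists whose genes vary together, as the estimated correlations show for many of the real lists.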

Results

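Expression was compared between differentiated preadipocytes in which Cre recombinase had been activated to delete Tcf7l2 and cells of the same floxed line given only the solvent. Tcf7l2 encodes a transcription factor of the TCF/LEF family, which acts with beta-catenin at Wnt target genes. Cells received 4-hydroxytamoxifen (3 libraries, termed knockout) or ethanol (3 libraries, termed control) for 24 h, starting 2 days before differentiation, and were differentiated with dexamethasone, isobutylmethylxanthine and insulin until day 8. The labels also list an agent at 5 nM, under a code number that increases by 1 from each library to the next, so that the control libraries hold the 3 lowest numbers and the knockout libraries the 3 highest. Whether the agent differed between libraries is not settled by the labels. Every knockout library came from 4-hydroxytamoxifen-treated cells and every control library from ethanol-treated cells, so deletion and drug treatment coincide. The labels do not say that the libraries of a group came from separate cultures, and the p-values measure the spread between these libraries, which may be technical.

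The control libraries held 33484764, 28071679 and 26621293 counts and the knockout libraries 30118550, 31520011 and 26764263. Between 22087 and 22602 genes had at least 1 count. The 10 genes with the most reads took from 11.6% to 12.2% of the counts. Pearson correlations of log2 CPM across genes were 0.995 to 0.996 for the 6 pairs of libraries within a group and 0.990 to 0.991 for the 9 pairs between groups. The first principal component held 51% of the variance and separated the groups. The second component (15.9%) set control replicate 3 (-15.1) and knockout replicate 2 (-14.1) apart from the other 4 libraries, which were all above 0, without separating the groups. The lipogenic gene Fasn (1209 and 2554 CPM), the Wnt feedback gene Axin2 (5.76 and 11.6 CPM) and the share of mt-Rnr2 (0.668% and 1.21% of counts) were each highest within their group in these libraries. No pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of 4.29 to 14.8 within groups, so none was treated as a library deposited again. This does not show whether they came from separate cultures.

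Tcf7l2 itself (ENSMUSG00000024985, GRCm38 chromosome 19, 55741820 to 55933654, plus strand) was present at 7.65 ± 1.49 CPM in control cells (SD, n = 3) and 6.12 ± 0.638 CPM in knockout cells (SD, n = 3). The log2 fold change was -0.32 (SE 0.14; edgeR adjusted p = 0.125). Control libraries ranged from 6.13 to 9.11 CPM and knockout libraries from 5.65 to 6.85 CPM. An exact 2-sided permutation test of the CPM values gave p = 0.2, where 3 libraries against 3 can give no less than 0.1. Without control replicate 2 the log2 fold change was -0.46 (edgeR adjusted p = 0.0322). The labels do not say which part of the gene was floxed, and counts over a whole gene do not measure the loss of single exons, so this value neither checks nor contradicts the genotype labels.

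Knockout cells differed widely from control cells, mostly by small steps. The genes with the largest falls included Cdkn1c, which encodes the cell cycle inhibitor p57, at 206 ± 25.7 CPM in control and 45 ± 5.29 CPM in knockout cells, 4.58-fold lower. Igfbp5, a secreted binding protein of insulin-like growth factors, fell from 527 ± 79.4 to 173 ± 16.8 CPM, 3.05-fold lower. The platelet-derived growth factor gene Pdgfd was 2.29-fold lower (79.5 ± 1.87 against 34.7 ± 1.94 CPM). Among called genes with an average log2 CPM of at least 2 and no overlap between the groups, the largest rise was that of Cidea, a lipid droplet protein of brown and beige adipocytes, from 2.3 ± 0.675 to 7.84 ± 2.63 CPM, 3.36-fold higher. In all, edgeR called 3346 of 14946 tested genes (22.4%): 1778 were higher and 1568 lower in knockout cells.

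Among the 10 largest falls, the transcriptional cofactor gene Lmo2 was 3.15-fold lower, Coro2a 2.72-fold, Limch1 2.6-fold, Ppef1 2.34-fold, the proprotein convertase gene Pcsk5 2.34-fold, the chondroitin sulfotransferase gene Chst13 2.31-fold and the semaphorin receptor gene Plxnc1 2.12-fold. Among the 10 largest rises, Serpinb6b was 3.16-fold higher, Adap1 2.65-fold, the carboxylesterase gene Ces1d 2.48-fold, Klhdc7a 2.41-fold, the proton channel gene Otop1 2.33-fold, the alkaline phosphatase gene Alpl 2.29-fold, Hephl1 2.27-fold, the D-aspartate oxidase gene Ddo 2.25-fold and Tspan15 2.25-fold. All of these had adjusted p-values of at most 0.0125 in edgeR. Ces1d and Serpinb6b belong to families of close paralogs, and their counts are uncertain to the extent that reads were shared. Cdkn1c (GRCm38 chromosome 7, 143458339 to 143461050, minus strand) shares 30.7% of its exonic bases with Gm44732 on the opposite strand, which was at 0.44 CPM.

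The median size of the called log2 changes was 0.34. At least a 2-fold change was fitted for 147 higher and 66 lower genes, and a test against a log2 change of 1 called 3: Cdkn1c, Ostn (4.26-fold lower, 4.86 ± 0.7 to 1.13 ± 0.251 CPM) and Alkal2, of which Ostn and Alkal2 were chosen after their values were seen. Without control replicate 1 the count of called genes was 2145, and without knockout replicate 3 it was 2178. No called gene changed sign in any alternative fit.

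**Figure D1:**
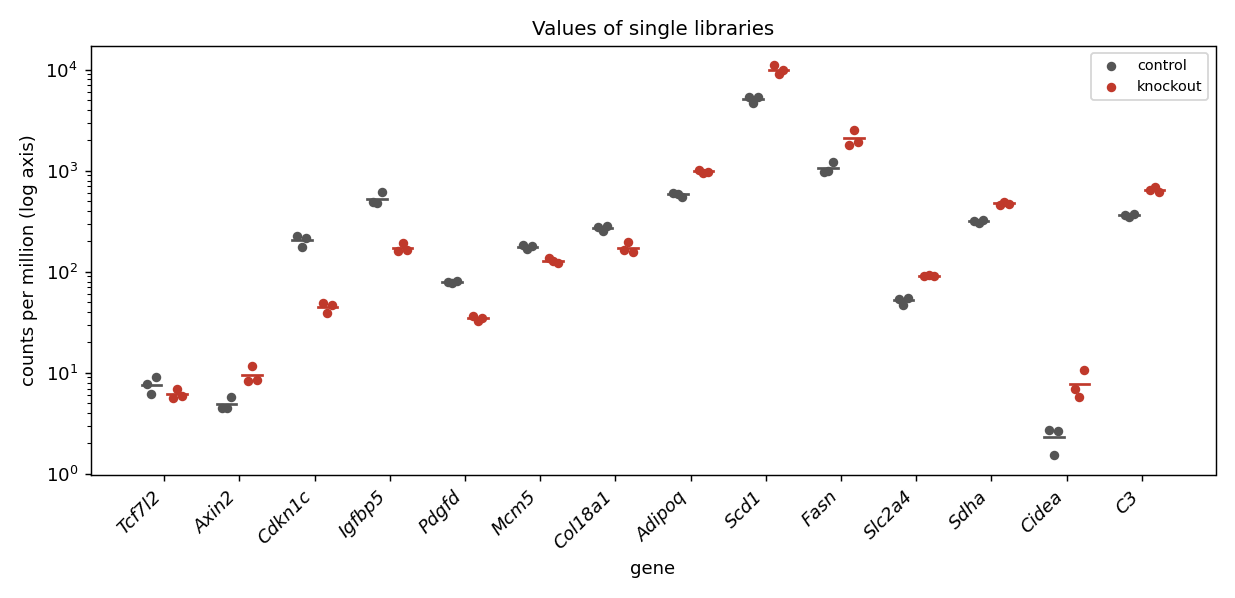
CPM (log axis) of 14 genes in each of the 3 control (grey) and 3 knockout (red) libraries, with a bar at the group mean. The groups overlap for Tcf7l2, while Cdkn1c lies at 206 ± 25.7 CPM in control and 45 ± 5.29 CPM in knockout libraries (SD, n = 3), and Adipoq and Scd1 lie higher in each knockout library than in any control library.

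Genes of mature adipocytes were higher in knockout cells. Of 34 tested genes of the adipocyte identity list, 25 rose, 1 fell and 8 were not called (28 called when adjusted over the list alone, 26 higher and 2 lower). Leptin (Lep) rose 3.81-fold from 0.598 ± 0.192 to 2.33 ± 0.377 CPM, Pck1, which encodes a key enzyme of glyceroneogenesis, 2.17-fold from 26 ± 3.21 to 56.3 ± 4.17 CPM, and the triglyceride lipase gene Pnpla2 1.95-fold from 110 ± 12.9 to 213 ± 26.8 CPM. The members named next, apart from Klf15, were chosen after their values were seen. Adiponectin (Adipoq; GRCm38 chromosome 16, 23146536 to 23158028, plus strand) rose 1.69-fold from 584 ± 26.5 to 986 ± 38 CPM, the lipid droplet genes Plin1 and Cidec both rose 1.68-fold, and the fatty acid binding protein gene Fabp4 rose 1.56-fold. Of the adipogenic transcription factor genes, Pparg rose by 0.32 (SE 0.055) and Cebpa by 0.51 (SE 0.056) on the log2 scale. Klf15 was the member that fell, 1.19-fold, and was not called without control replicate 2 (edgeR adjusted p = 0.0749) or knockout replicate 3 (0.0648), with adjusted p of 0.00797 to 0.0749 across the alternatives. Lpl, lipoprotein lipase, was at 2066 ± 61.6 and 2119 ± 249 CPM and was not called (log2 fold change 0.036, SE 0.072; edgeR adjusted p = 0.769). The list's median log2 fold change was 0.71 (limma's camera, adjusted p = 3.40e-14; adjusted p = 0.0518 with an estimated correlation).

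Both synthesis and breakdown of fat were represented among the rises. Of 26 tested genes of fatty acid and triglyceride synthesis, 22 rose, 1 fell and 3 were not called (24 called when adjusted over the list alone). Fatty acid synthase (Fasn) rose 1.98-fold from 1060 ± 129 to 2099 ± 398 CPM, and the acetyl-CoA synthetase gene Acss2 1.93-fold. The desaturase gene Scd1 rose from 5120 ± 383 to 10035 ± 947 CPM (log2 fold change 0.97, SE 0.074). The elongase gene Elovl6 fell 1.26-fold. The list's median log2 fold change was 0.61 (camera adjusted p = 3.68e-12; adjusted p = 0.137 with an estimated correlation). Of 28 genes of lipolysis and fatty acid oxidation, 26 rose, 1 fell and 1 was not called (27 called when adjusted over the list alone). The nuclear receptor gene Ppara rose 2.06-fold and Cpt1b, the gene of a mitochondrial fatty acid importer, 1.94-fold, while the thioesterase gene Acot2 fell 1.19-fold. The median log2 fold change was 0.60 (camera adjusted p = 2.01e-16; adjusted p = 0.186 with an estimated correlation).

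Most tested genes of oxidative phosphorylation were higher in knockout cells. Of 49 nuclear genes of oxidative phosphorylation, 44 rose, 0 fell and 5 were not called (45 higher when adjusted over the list alone), among them cytochrome c (Cycs, 1.51-fold), the succinate dehydrogenase gene Sdha (1.5-fold, 316 ± 13 to 476 ± 18 CPM) and Uqcrfs1 (1.46-fold). Their median log2 fold change was 0.37 (camera adjusted p = 1.23e-20; adjusted p = 0.201 with an estimated correlation). Of 13 messenger RNAs encoded by mitochondrial DNA, 7 were tested and 6 rose, in both adjustments. Among them, mt-Nd2 was 1.56-fold, mt-Nd4 1.46-fold and mt-Nd1 1.43-fold higher (median log2 fold change of the list 0.43, camera adjusted p = 5.10e-05, adjusted p = 0.201 with an estimated correlation). The untested members did not pass the filter on low counts. Whether they were low in the cells, or lost reads that map to several places, was not tested. The share of all counts from the mitochondrial chromosome was 1.06% to 1.22% in control and 1.67% to 1.98% in knockout libraries. This share would miss any reads lost because they map to several places. The share includes ribosomal RNA, of which the libraries had been depleted. It and the values of mt-Rnr2 given next may therefore reflect what the depletion left, which was not tested. The mitochondrial ribosomal RNA gene mt-Rnr2, chosen after its values were seen, took 0.501% to 0.668% of all counts in control and 0.896% to 1.21% in knockout libraries (log2 fold change 0.79, SE 0.15; edgeR adjusted p = 0.0142), and was not called without a filter on low counts (adjusted p = 0.0863). Of 22 tested brown and beige adipocyte genes, 13 rose, 0 fell and 9 were not called, with the same numbers when adjusted over the list alone. Besides Cidea and Otop1, Cox8b rose 2.18-fold from 22 ± 4.89 to 47.8 ± 3.26 CPM. Chosen after their values were seen, the regulator genes Ppargc1a (1.5-fold) and Prdm16 (1.3-fold) were called higher, Ppargc1a not without control replicate 1 or 2 or knockout replicate 2 or 3 (adjusted p up to 0.141) and Prdm16 not by DESeq2 (adjusted p = 0.101) or without any 1 of the control replicates or knockout replicate 2 or 3. The uncoupling protein gene Ucp1, also chosen after its values were seen, was at 18.2 ± 5.29 and 30 ± 9.28 CPM and was not called (log2 fold change 0.72, SE 0.34; edgeR adjusted p = 0.216). The list's median log2 fold change was 0.63 (camera adjusted p = 4.25e-07; adjusted p = 0.201 with an estimated correlation). Without knockout replicate 1 Otop1 was no longer called (edgeR adjusted p = 0.0528, the highest of its alternatives).

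Of 27 genes of insulin signalling and glucose uptake, 13 rose, 2 fell and 12 were not called (16 called when adjusted over the list alone). The insulin-responsive glucose transporter gene Slc2a4 rose 1.75-fold from 52.2 ± 4.23 to 91.2 ± 0.897 CPM and Tbc1d4, which regulates that transporter's traffic, 1.65-fold. The kinase genes Sgk1 and Akt1 fell, 1.23-fold and 1.12-fold, and Akt1 was not called without control replicate 1, control replicate 2 or knockout replicate 3 (adjusted p of 0.0586, 0.0658 and 0.0930). Chosen after their values were seen, the insulin receptor gene Insr rose 1.26-fold, and Irs2 was at 14 ± 2.17 and 18.2 ± 3.23 CPM and was not called (edgeR adjusted p = 0.0769; it was called without a filter on low counts, adjusted p = 6.81e-05, in DESeq2, 0.0215, and without control replicate 3, 0.0199). The list's median log2 fold change was 0.20 (camera adjusted p = 5.78e-04; adjusted p = 0.201 with an estimated correlation). Of 22 glycolysis genes, 4 rose and 18 were not called, in both adjustments. Gapdh, not called, was at 16.9 ± 2.55 CPM in control libraries, and Aldoa, called higher, at 1259 ± 127 CPM. Whether Gapdh lost reads that map to several places was not tested. Ldhb was 1.43-fold, Pfkfb3 1.4-fold and Hk2 1.34-fold higher. The median log2 fold change was 0.25 (camera adjusted p = 0.00121, adjusted p = 0.524 with an estimated correlation, fry adjusted p = 0.0964). With 1 library left out, this median ran from 0.14 to 0.33.

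Among TCF/LEF family members and Wnt/beta-catenin target genes, 5 of 21 tested rose, 1 fell and 15 were not called (7 called when adjusted over the list alone). Axin2, a feedback inhibitor of the pathway (GRCm38 chromosome 11, 108920349 to 108950783, plus strand), rose 1.94-fold from 4.9 ± 0.749 to 9.44 ± 1.84 CPM. The feedback gene Nkd2 rose 1.63-fold and Ccn5 1.47-fold, and Ccn4 fell 1.44-fold from 86 ± 1.11 to 59.6 ± 1.55 CPM. Notum, which encodes an enzyme that inactivates Wnt proteins, was chosen after its values were seen and rose 2.66-fold at a low level, with 14, 10 and 3 counts in the control and 26, 25 and 21 in the knockout libraries. Ccn5 was not called without knockout replicate 2 (edgeR adjusted p = 0.0515, the highest of its alternatives). The list as a whole did not pass (median log2 fold change 0.13; camera adjusted p = 0.118; adjusted p = 0.549 with an estimated correlation), but it did without a filter on low counts (adjusted p = 0.0439) and without knockout replicate 1 (adjusted p = 0.0386); across the alternatives the adjusted p was 0.0386 to 0.549 for the TCF/LEF family and Wnt/beta-catenin target genes. Chosen after their values were seen, Tcf7 was at 0.258 ± 0.102 and 0.41 ± 0.211 CPM and Tcf7l1 at 3.51 ± 0.181 and 3.67 ± 0.791 CPM, neither called, and Lef1 was too low to be tested.

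Of 33 tested Wnt ligands, receptors and secreted modulators, 11 rose, 2 fell and 20 were not called, in both adjustments. Sfrp2, a secreted Wnt antagonist, rose 2.18-fold from 28.9 ± 2.33 to 62.8 ± 14.7 CPM and the ligand gene Wnt11 1.53-fold. Wnt4 rose 1.64-fold but was not called without control replicate 1 or 3 or knockout replicate 1 or 3, nor by DESeq2 (adjusted p = 0.129), limma-voom or with total count scaling (adjusted p of 0.0137 to 0.227 across the alternatives). The co-receptor gene Ror2 fell 1.23-fold and Rspo1 1.36-fold, and Rspo1 was not called by DESeq2 (adjusted p = 0.102) or without control replicate 1 or 2 or knockout replicate 2 or 3 (0.0185 to 0.114 across the alternatives). The list's median log2 fold change was 0.073 (camera adjusted p = 0.0237; adjusted p = 0.404 with an estimated correlation). Without control replicate 1 or knockout replicate 2 its adjusted p was 0.0604 and 0.0682.

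**Figure D2:**
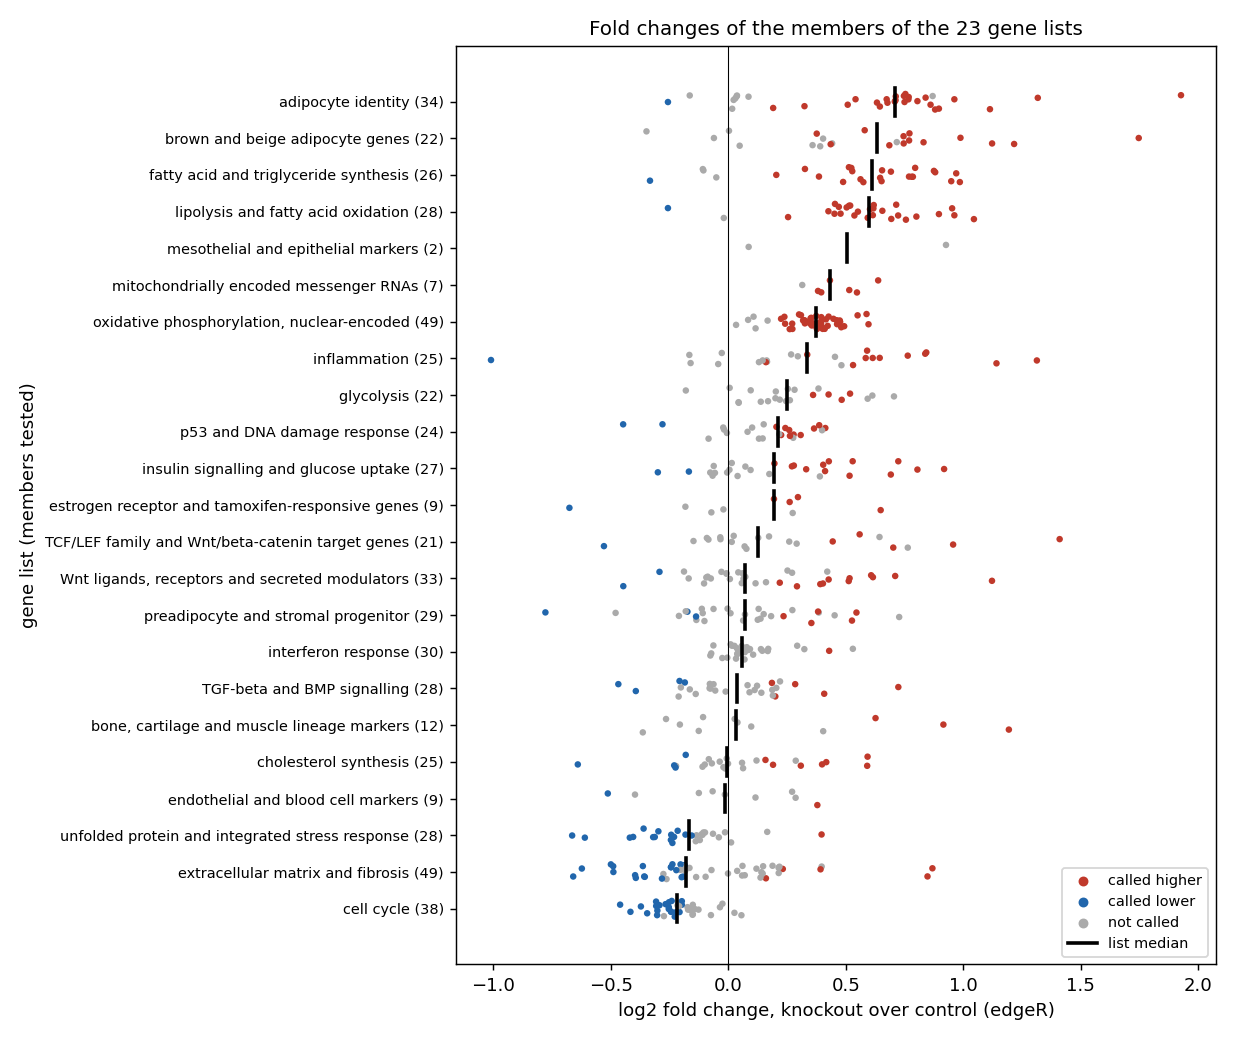
Log2 fold changes, knockout over control, of the tested members of the 23 gene lists (1 point per gene, red called higher, blue called lower, grey not called; vertical placement within a list is random), ordered by list median (black bar). The median is 0.71 for the adipocyte identity list and -0.22 for the cell cycle list.

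Of 49 extracellular matrix and fibrosis genes, 19 fell, 5 rose and 25 were not called (22 lower and 10 higher when adjusted over the list alone). Periostin (Postn), second in the list by CPM, which is not scaled for transcript length, fell 1.41-fold from 19473 ± 1255 to 13771 ± 667 CPM. The collagen gene Col18a1 fell 1.58-fold and the protease gene Fap 1.54-fold. Col3a1, chosen after its values were seen, fell 1.22-fold from 24963 ± 552 to 20526 ± 768 CPM. Col8a1 rose 1.83-fold and the metalloproteinase inhibitor genes Timp3 and Timp1 rose 1.8-fold and 1.31-fold. Its median log2 fold change was -0.18 (camera adjusted p = 0.0217; adjusted p = 0.530 with an estimated correlation; fry adjusted p = 0.0964). Its adjusted p was 0.0833 without control replicate 3, 0.0608 without knockout replicate 1 and 0.0640 without knockout replicate 3.

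Preadipocyte and stromal progenitor genes showed no common direction: 5 of 29 rose, 3 fell and 21 were not called (10 called when adjusted over the list alone; median log2 fold change 0.071; camera adjusted p = 0.519). Klf4 was 1.46-fold, Cd24a 1.44-fold and Sema3c 1.3-fold higher. The ecto-nucleotidase gene Nt5e was 1.72-fold, Vcam1 1.13-fold and Thy1 1.1-fold lower. Cd24a was not called without control replicate 1 or 3 or knockout replicate 2 or 3 (adjusted p up to 0.117), Vcam1 without control replicate 2 or knockout replicate 3 (up to 0.0978), and Thy1 in 9 of 13 alternatives (up to 0.141), among them each library left out but knockout replicate 2. The preadipocyte marker Pdgfra, chosen after its values were seen, was at 1247 ± 22.6 and 1135 ± 44.8 CPM and was not called by edgeR (adjusted p = 0.0593), but was called lower by DESeq2 (adjusted p = 0.0466), limma-voom (0.0442) and with total count scaling (0.0452). Of 28 TGF-beta and BMP signalling genes, 5 rose and 4 fell, in both adjustments. Ltbp1 was 1.65-fold, Inhbb 1.33-fold and Ltbp2 1.22-fold higher, and Bambi was 1.38-fold, Bmper 1.31-fold and Fstl1 1.15-fold lower. Ltbp2 was not called without any 1 of control replicates 1 and 2 and knockout replicates 2 and 3 (adjusted p of 0.0746 to 0.156). The list's median (0.035) and mean (0.029) log2 fold changes were above 0 and its camera direction was down (adjusted p = 0.963).

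Markers of other cell types were few and mixed. Of 25 endothelial and blood cell markers, which the sort was meant to exclude, 9 were abundant enough to test. The receptor gene Kdr rose 1.3-fold and Egfl7 fell 1.43-fold (8.15 ± 0.221 to 5.72 ± 0.18 CPM), sharing 1.79% of its exonic bases with the far more abundant Agpat2 on the opposite strand (median log2 fold change -0.014; camera adjusted p = 0.814). Of 12 tested bone, cartilage and muscle markers, 3 rose: Alpl, Des (1.89-fold) and Sox6 (1.54-fold; not called by DESeq2, adjusted p = 0.107, nor without control replicate 1 or 3 or knockout replicate 3, with adjusted p up to 0.145). The list did not pass camera (adjusted p = 0.490) and passed fry (adjusted p = 0.0225). Of 14 mesothelial and epithelial markers, 2 were tested and neither was called: Krt19 was at 19.1 ± 0.646 and 20.4 ± 1.83 CPM and Lrrn4 at 0.326 ± 0.163 and 0.646 ± 0.0195 CPM (camera adjusted p = 0.265). Lrrn4 passed when adjusted over the list alone, in limma-voom (adjusted p = 0.0421) and without control replicate 1 (0.0246), with 0.214 the highest of its alternatives.

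Genes of the cell cycle were lower in knockout cells by small amounts. Of 38, 21 fell, 0 rose and 17 were not called (29 lower when adjusted over the list alone). The largest falls were of DNA replication genes, with Mcm5 1.38-fold lower (177 ± 7.62 to 129 ± 6.8 CPM), Gins2 1.33-fold and Mcm2 1.29-fold. Gins2 shares 67.3% of its exonic bases with Gse1 on the opposite strand, which was at 6.07 CPM against 47.8 CPM for Gins2. The proliferation marker Mki67, chosen after its values were seen, was at 173 ± 12.6 and 156 ± 9.74 CPM and was not called (edgeR adjusted p = 0.0977), but was called lower without control replicate 2 (0.0276) or knockout replicate 1 (0.0380). For the list, the median log2 fold change was -0.22 (camera adjusted p = 8.91e-09; adjusted p = 0.382 with an estimated correlation). Of 24 genes of the p53 and DNA damage response, 10 rose, 2 fell and 12 were not called, in both adjustments. Cdkn1a, which encodes the cell cycle inhibitor p21, rose 1.29-fold, and the death receptor genes Fas and Tnfrsf10b rose 1.33-fold and 1.31-fold, while Gadd45a fell 1.36-fold and Plk2 1.21-fold. Gadd45a shares 19.1% of its exonic bases with E230016M11Rik on the opposite strand, which was at 1.27 CPM against 29.6 CPM for Gadd45a. Fas was not called without control replicate 1 or knockout replicate 1 or 3 (adjusted p up to 0.0753), nor Tnfrsf10b without control replicate 1 or 3 or knockout replicate 3 (up to 0.0982). The median log2 fold change was 0.21 (camera adjusted p = 0.00990; adjusted p = 0.524 with an estimated correlation; fry adjusted p = 0.0706).

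Of 28 genes of the unfolded protein and integrated stress response, 15 fell, 1 rose and 12 were not called (21 lower when adjusted over the list alone). The cystine transporter gene Slc7a11 fell 1.59-fold, the pseudokinase gene Trib3 1.53-fold and the transcription factor gene Ddit3 1.34-fold, and the chaperone gene Dnajb9 rose 1.32-fold. Over the list the median log2 fold change was -0.17 (camera adjusted p = 4.09e-07; adjusted p = 0.0518 with an estimated correlation). Of 25 tested inflammation genes, 12 rose, 1 fell and 12 were not called (18 called when adjusted over the list alone). The neutrophil chemokine gene Cxcl5 rose 2.49-fold to 1.98 ± 0.354 CPM, the acute-phase gene Orm1 1.79-fold and complement component C3 1.79-fold from 362 ± 15.1 to 648 ± 38.3 CPM, while the interleukin-1 receptor antagonist gene Il1rn fell 2.01-fold. C3 and Orm1 are also expressed by adipocytes. The median log2 fold change was 0.34 (camera adjusted p = 1.17e-04; adjusted p = 0.201 with an estimated correlation). Of 30 interferon response genes, 1 rose (Ifi27, 1.35-fold) and 29 were not called, in both adjustments (camera adjusted p = 0.169). The interferon list passed without control replicate 3 (adjusted p = 4.10e-04) and without knockout replicate 1 (adjusted p = 0.00547), with 0.925 the highest of its alternatives.

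Cholesterol synthesis genes moved both ways, with 7 of 25 higher, 4 lower and 14 not called (12 called when adjusted over the list alone; camera adjusted p = 0.572; median log2 fold change -0.0064, mean 0.050). Insig1 was 1.51-fold, Pmvk 1.51-fold and Lss 1.34-fold higher, and Mvk and Msmo1 were both 1.17-fold lower. Of 9 tested oestrogen receptor and tamoxifen-responsive genes, 4 rose and 1 fell, in both adjustments (camera adjusted p = 0.490). Rerg was 1.57-fold, the protease gene Ctsd 1.23-fold and the oestrogen receptor gene Esr1 1.2-fold higher, and the oestrogen-responsive gene Greb1 was 1.6-fold lower. Esr1 was not called without control replicate 1 (adjusted p = 0.119) or 2 (0.0800). Camera called 14 of the 23 lists, 11 higher and 3 lower, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Fry called 12.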

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

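All alternatives but 1 were planned before the data were examined. The 3346 called genes became 3323 with DESeq2 size factors, 3336 with limma-voom and 2797 with DESeq2, of which 3300, 3284 and 2728 were among the original calls. No original call changed sign in these or the other scalings, filters and left-out libraries. At an adjusted p under 0.01 there were 1105 higher and 829 lower calls, fewer by construction, and glmTreat against a log2 change of 1 called 3 (1 higher, 2 lower). Leaving out 1 library gave 2145 to 3475 calls, 1222 to 1829 higher and 923 to 1646 lower. The lowest counts came without control replicate 1 (923 lower) and without knockout replicate 3 (925 lower); fewer samples were then tested, and the cause of the difference between libraries was not tested. Without control replicate 3 and knockout replicate 2 together, an alternative chosen after seeing the data, 3957 genes were called (2044 higher, 1913 lower), 3027 of them among the original calls. Tcf7l2 had log2 fold changes of -0.46 to -0.19 with 1 library left out and was called only without control replicate 2 among its 13 alternatives; the cause was not tested. The count of called lists went from 14 to 0 with an estimated correlation. In most lists the estimate exceeded the preset 0.01, as in oxidative phosphorylation (0.439) and the cell cycle (0.440), and camera then allows a larger error. The stress response list lost its call too, with an estimate of -0.00773. Its unadjusted camera p was 1.07e-07 with the preset correlation and 0.00390 with the estimate. With an estimated correlation camera also draws its degrees of freedom from the libraries, which are few, and not from the genes. The fall to 0 calls is therefore not due to higher correlations alone. How much each part contributed was not tested. Of 137 other genes taken through the alternatives, 112 kept their direction and side of the threshold in all alternatives and 18 lost a call in at least 1. Directions reversed for 3 genes that were not called, with a library left out: Lpl (-0.065 to 0.088; below 0 without knockout replicate 1), Acp1 (-0.057 to 0.079; -0.011 without control replicate 3 and -0.057 without knockout replicate 1) and Tcf7l1 (-0.11 to 0.19; below 0 without knockout replicate 2), with the cause not tested. Genes with a few counts per library, such as Notum, limit what this depth can show of low Wnt targets. No paired analysis was possible because the labels give the groups no shared replicate numbers.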

Other observations

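Genes and tests in this part were chosen after the results were seen, except the GC and length tests, the chromosome test and the splits of the samples. The gene with the largest fitted rise was Alkal2, which encodes a ligand of the receptor tyrosine kinases ALK and LTK (GRCm38 chromosome 12, 30884322 to 30893854, plus strand). It had 2, 1 and 1 counts in the control and 95, 98 and 52 in the knockout libraries. From the summed counts of 4 and 245 the ratio of CPM was 61.1 (95% exact binomial interval 23.6 to 226, covering counting error only). Its exons share 35.1% of their bases with Acp1 on the opposite strand, which was at 11.5 ± 0.515 and 11.7 ± 1.18 CPM (SD, n = 3) and was not called.

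Igfbp6, which encodes a binding protein of insulin-like growth factors, was 1.36-fold lower (709 ± 17.4 to 520 ± 11.2 CPM), beside the fall of Igfbp5, while Igf1 rose 1.38-fold (147 ± 8.61 to 202 ± 2.98 CPM) and Igf2 2.55-fold at a low level (0.735 ± 0.0165 to 1.88 ± 0.203 CPM). Besides Cdkn1c, the imprinted genes Plagl1 and Mest were 1.63-fold and 1.38-fold lower, while Igf2 is imprinted too and rose, and other imprinted genes were not examined as a group. Mest was not called without control replicate 1 or 2 or knockout replicate 1 or 3 (edgeR adjusted p of 0.0504 to 0.106). Mest shares 23.1% of its exonic bases with Copg2 on the opposite strand, which was at 60.1 CPM against 5.43 CPM for Mest. Apoc1 rose 2.03-fold, Apoe 1.52-fold and Angptl8, a secreted regulator of lipoprotein lipase, 1.75-fold, while Lpl itself was not called. The collagen chaperone gene Serpinh1 fell 1.33-fold (2691 ± 50.8 to 2016 ± 35.9 CPM).

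The 3346 genes called by edgeR stand against at most 0 in the other splits of the 6 samples into 3 and 3. At an unadjusted p under 0.05 there were 5096 genes against at most 1194. Every other split mixes control and knockout libraries, so any difference between the groups widens its spread and few calls are expected there. The contrast therefore does not bear on the cause of the difference. The 10 splits, of which 1 gave as many, are also too few for a share under 0.05. A gain or loss of a whole chromosome in the knockout cells is argued against: the median log2 fold change of each chromosome with at least 100 tested genes lay within 0.0499 of that of all genes.

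The first pattern is the joint rise of adipocyte, lipid and mitochondrial genes. A GC or transcript length trend is argued against, since the median of the pooled 135 members of 4 of these lists kept 98.2% of its size (0.48 before, 0.47 after, standard error 0.028) once a smooth trend was removed. A larger share of differentiated cells, each unchanged, may account for part of it. Adipoq rose the most of Adipoq, Plin1 and Cidec. Of 34 adipocyte list members, 2 (Lep and Pck1) lay above Adipoq by more than a 95% limit on their combined SE. Another 20, these 3 genes included, lay within that limit and 12 below it. Among those below it, Klf15 fell and Lpl was not called (log2 fold change 0.036). The preadipocyte and stromal progenitor list showed no common direction (median log2 fold change 0.071, camera adjusted p = 0.519). The extracellular matrix list (median -0.18, camera adjusted p = 0.0217) and the cell cycle list (-0.22, camera adjusted p = 8.91e-09) were lower. Neither passed camera with an estimated correlation (adjusted p of 0.530 and 0.382). Over all tested genes 73 lay above Adipoq by that limit, and 14 after adjustment over all tested genes (1-sided normal test). These genes were picked by the margin that is tested, and few are members of the adipocyte list. They therefore do not decide the explanation, which stays open. Whether 4-hydroxytamoxifen, Cre activity or the loss of Tcf7l2 brought the rise was not tested, since no group separates them. The agent listed under a code number in the labels stays open too. Its numbers were all lower in control than in knockout libraries, and the labels do not settle whether it differed.

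The second pattern is the rise of the Wnt feedback genes Axin2 and Notum in cells meant to lack a TCF factor. Their list as a whole did not pass camera (adjusted p = 0.118), though it did without a filter on low counts and without knockout replicate 1. Of 21 tested members, 5 rose, Ccn4 fell and 15 were not called. Besides Axin2 and Notum, the members that rose were Nkd2 (log2 fold change 0.70), Ccn5 (0.56) and Apcdd1 (0.44). Those not called include Nkd1 (log2 fold change 0.26, edgeR adjusted p = 0.0602) and Znrf3 (-0.084, edgeR adjusted p = 0.566). Nkd1 passed when adjusted over the list alone (edgeR adjusted p = 0.0435). Replacement by Tcf7, Lef1 or Tcf7l1 could account for it and stays open. Neither tested member was called. The upper 95% bound of the log2 fold change was 0.41 for Tcf7l1, below the rise of Axin2 (0.96). For Tcf7 it was 1.64, because that gene was near the limit of detection, and Lef1 was too low to be tested. Replacement without a rise in messenger RNA was not tested. A larger share of differentiated cells also stays open, since Axin2 lay only 1.29 combined SE above Adipoq. The loss of Tcf7l2 itself, which the design names, stays open and was not tested apart from the drug. Nor was it tested apart from the agent in the labels, should that agent have differed between the groups.

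The third pattern is the small fall of cell cycle genes beside a small rise of p53 target genes. A GC or length trend is argued against for the cell cycle list, which kept 97.8% of its median after correction. A larger share of differentiated cells, raised above for the other patterns, was not tested for this one and stays open. A response to 4-hydroxytamoxifen or to active CreERT2 as such, which may damage DNA, cannot be told apart from the loss of Tcf7l2. No cells without floxed Tcf7l2 were given the drug among the samples analysed here. An effect of the agent in the labels cannot be told apart either, should that agent have differed between the groups. The unadjusted camera value of the p53 list, 0.00516, only restates the pattern, and the list was not called with an estimated correlation (limma adjusted p = 0.524) or by fry (adjusted p = 0.0706). SV40 large T antigen, with which these cells were immortalised, binds p53.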
